A study of Homo sapiens with 18 samples.

How the data were processed

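Bulk MARS-seq libraries were made from RNA extracted with the RNeasy kit, in 18 libraries of the WIBR3 line covering 2 genotypes (LIS1+/+ and LIS1+/-) at 3 stages (hESC, organoid Day 5 and organoid Day 12), with 3 libraries in each of the 6 groups. Per the submitters' processing notes, the authors used cutadapt, STAR and DESeq2, with versions not stated, and the notes name the builds GRCh37 and hg38 without saying which was used for what. The deposited files hold raw counts per gene symbol, 1 file per library, with no normalization, as whole numbers over 26485 gene rows and 5 closing rows in the layout of htseq-count. Whether molecular identifiers were collapsed, and whether counting used the strand, is not given in the sources used here. The gene rows of a library summed to between 1425098 and 4501489 counts.

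Genes were filtered with filterByExpr on the 6 groups, which left 12215, and scaled with TMM. They were tested with the quasi-likelihood F-test of edgeR 4.0.16 (robust fit, R 4.3.3) in 1 fit of all 18 libraries with 1 coefficient per group and 12 residual degrees of freedom. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. The 10 comparisons were LIS1+/- against LIS1+/+ at each stage, successive stages within each genotype, and the differences of the genotype effect between stages. All tests were two-sided. CPM values use the TMM library sizes, and errors are the SD of the libraries or the SE of the fitted log2 fold change. A fold against a group with no count was computed against a floor of 3 counts over the group. With 1 to 3 counts, the ratio of pooled counts is given with its 95% counting interval.

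Before the data were examined, the comparisons, tests, alternatives, gene lists and the rule for named genes were fixed. The rule named PAFAH1B1 always. For each genotype comparison it took the 10 genes with the largest rise and the 10 with the largest fall in log2 fold change among those that passed, had a mean of at least 10 CPM in the higher group and showed no overlap between the libraries of both groups. For the 2 wild-type stage comparisons it took 8 and 8. It also took genes that passed at all 3 stages in 1 direction, the 5 with the smallest p in each direction for each difference of effects, and up to 4 members of each list by smallest adjusted p. Unnamed loci, long intergenic, micro and small nucleolar RNAs were left out, as were XIST, TSIX and Y-linked genes. The text does not print every gene that the rule took, and counts of named genes include those not printed.

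Of 32 gene lists written from textbook knowledge, 31 were tested with camera of limma 3.58.1 (preset inter-gene correlation 0.01, lists of at least 5 tested members, adjusted over the lists of a comparison). The list of mitochondrially encoded genes was not tested because none of them is in the files. Camera with an estimated correlation and fry, which asks whether the genes of a list move 1 way on balance, served as alternatives. Member counts are given over all genes and adjusted over the list alone. A list said to move through genes had them among its members called over all genes, while camera tests all members together. List medians are also given, where they differ, with members that had no count in a group set at their bound.

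The other alternatives were DESeq2 size factors in place of TMM, no filter beyond 1 count, DESeq2 1.42.0 in place of edgeR, a fit of only the libraries compared, the replicate number as a block, and each library left out in turn. After seeing the data 2 alternatives were added: leaving out together the 3 libraries that stood apart, and removing the trend with GC content. GC content was taken from the last 500 bases of transcripts in GENCODE release 29, which gave a value for 11661 of the 12215 tested genes (95.5%). Gene positions came from a copy of GRCh38 whose build need not be that of the authors.

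The pipeline was tested on simulated data in which 200 genes were changed, some 2-fold and the others 4-fold, beside a planted list of 30 genes. Of the genes changed 2-fold edgeR recovered 42% in hESC, 51% at Day 5 and 47% at Day 12, and of those changed 4-fold 79%, 86% and 83%. For differences of the effect between stages it recovered 14%, 18% and 10% at 2-fold. Of the genes it called, 4.11%, 3.16% and 2.76% were unchanged ones in the genotype comparisons of hESC, Day 5 and Day 12. This share was 7.23% for Day 5 minus hESC, 7.69% for Day 12 minus Day 5 and 6.85% for Day 12 minus hESC. From hESC to Day 5 and from Day 5 to Day 12 the share was 3.75% and 6.16% in LIS1+/+. In LIS1+/- it was 7.10% and 7.24%. Outside the genotype comparisons, all but the 3.75% exceeded the adjusted p threshold, on 5 to 11 unchanged genes. Figures were drawn with Matplotlib 3.10.9 in Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3.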

Results

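RNA was sequenced from WIBR3, a human embryonic stem cell (hESC) line, in a LIS1+/+ and a LIS1+/- form, and from organoids grown from each. MARS-seq, the method used, counts tags near the 3' ends of transcripts in bulk RNA. LIS1, whose gene symbol is PAFAH1B1, regulates the motor protein dynein, and loss of 1 copy in people causes lissencephaly, a malformation in which the cortex lacks its folds. The 18 libraries formed 6 groups of 3: both genotypes as hESC, as organoids at Day 5 and as organoids at Day 12.

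Counts over genes per library ranged from 1602532 to 2386061 in hESC LIS1+/+, from 1839347 to 2984093 in hESC LIS1+/-, from 4216835 to 4501489 in Day 5 LIS1+/+, from 2586073 to 3365342 in Day 5 LIS1+/-, from 1425098 to 1962218 in Day 12 LIS1+/+ and from 1513390 to 3237210 in Day 12 LIS1+/-. Between 13590 and 15281 genes had at least 1 count in a library. The share of alignments that the files set aside as not unique averaged 52.9% in hESC LIS1+/+ and 42.8% in hESC LIS1+/-, and lay between 27.3% and 32.5% in the other 4 groups. File names carry a different pool number for each stage, so a change between stages cannot be told apart from a change between pools. Which part of LIS1 was altered, and from how many clones the LIS1+/- libraries came, is not given in the sources used here, so genotype and clone cannot be told apart either. The file names of the 3 LIS1+/- hESC libraries all carry the number 1 where those of the other groups count from 1 to 3, and what that number marks is not stated. In 3 libraries, hESC LIS1+/+ replicate 3, Day 5 LIS1+/- replicate 2 and Day 12 LIS1+/+ replicate 2, counts fell with the GC content of the genes relative to the other libraries of the stage, with slopes of -0.0167, -0.0207 and -0.0245 log2 per percent against -0.00223 to 0.0104 in the other libraries, and these 3 stood apart together on the third principal component. Counting intervals and floors in the text cover counting error only, while the confidence intervals of PAFAH1B1 come from the SE of the fit. The labels do not say that the 3 libraries of a group are separate cultures, and the p-values measure only the spread between these libraries.

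The targeted gene was measured lower in LIS1+/- at each stage. PAFAH1B1 lies on chromosome 17 of GRCh38, from position 2593210 to 2685615 on the plus strand. In hESC it stood at 84.8, 72.1 and 111 CPM (counts scaled to the size of each library) in the 3 LIS1+/+ libraries and at 61.2, 51.4 and 55.9 CPM in the 3 LIS1+/- libraries. At Day 5 the levels were 130, 134 and 152 CPM against 89.0, 105 and 84.3 CPM. At Day 12 they were 147, 218 and 140 CPM against 104, 114 and 76.1 CPM. Every LIS1+/- library lay below every LIS1+/+ library of its stage.

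The fitted PAFAH1B1 level in LIS1+/- was 62.7% of LIS1+/+ in hESC (95% confidence interval 46.8 to 84.1%), 66.7% at Day 5 (50.8 to 87.6%) and 58.2% at Day 12 (44.1 to 76.9%). The log2 fold change was -0.67 ± 0.21 (SE, n = 3 against 3, adjusted p = 0.173 over all genes) in hESC, -0.58 ± 0.19 (adjusted p = 0.148) at Day 5 and -0.78 ± 0.20 (adjusted p = 0.0372) at Day 12, so that PAFAH1B1 passed the threshold over all genes at Day 12 and not at the other stages. Adjusted over the 3 stages alone, the p-values were 0.00446, 0.00516 and 0.00137. A difference between the stages in this effect was not shown, with values of 0.09 ± 0.28 (adjusted p = 0.935) for Day 5 minus hESC, -0.20 ± 0.27 (adjusted p = 0.812) for Day 12 minus Day 5 and -0.11 ± 0.28 (adjusted p = 0.967) for Day 12 minus hESC. Because tags lie near the 3' end, they need not overlap the altered part of the gene, and the values do not measure protein. The Day 12 call was lost without LIS1+/+ replicate 1 (-0.87) or 2 (-0.55), without LIS1+/- replicate 1 (-0.82), 2 (-0.91) or 3 (-0.62), and in a fit of the Day 12 libraries alone (-0.80).

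**Figure D1:**
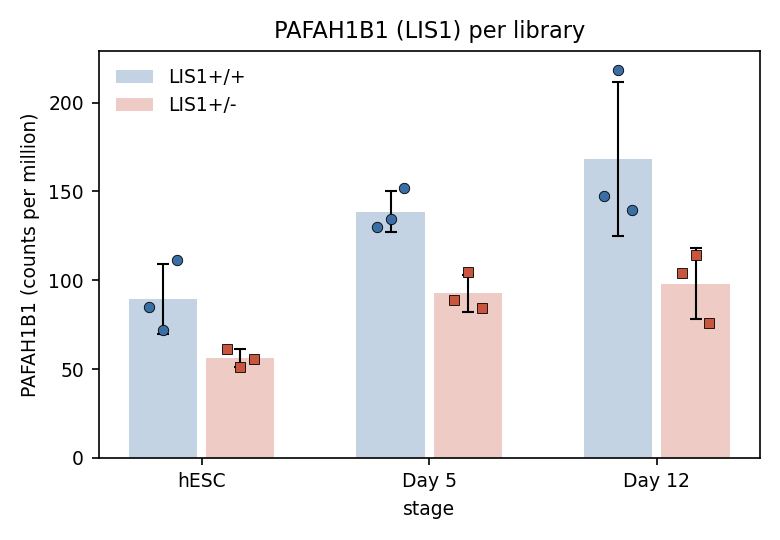
PAFAH1B1 (LIS1) level in CPM (vertical axis) by stage (horizontal axis) and genotype, with a point for each library, bars at the mean and error bars of 1 SD. The 3 LIS1+/- libraries lie below the 3 LIS1+/+ libraries at each stage, with means of 56.2 against 89.3, 92.6 against 139 and 98.1 against 168 CPM.

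The first question for the wild-type line was how expression changed on the way from stem cells to organoids. From hESC to Day 5 in LIS1+/+, regulators of the forebrain appeared that had no count in hESC. EMX2, a homeobox gene of the dorsal telencephalon, reached 150 ± 26.7 CPM (SD, n = 3), at least 261-fold above hESC. WNT8B, a ligand of the cortical hem, reached 96.2 ± 23.3 CPM (at least 167-fold). BARHL1, a homeobox gene of the diencephalon and hindbrain, reached 52.1 CPM (at least 90.6-fold), and C9orf171 reached 153 ± 36.0 CPM (at least 264-fold). The antisense transcripts EMX2OS (at least 209-fold) and ZNF503-AS2 (at least 96.0-fold) were also at 0 in hESC, and because the strand used for counting is not stated, part of their counts may belong to the genes opposite. WNT7B, which had 1 count in hESC, rose 1099-fold (counting interval 197 to 43441), and HES5, a Notch target of neural progenitors, rose from 1.24 to 989 CPM (log2 fold change 9.48 ± 0.86).

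Genes of the stem cell state and of the contractile cytoskeleton fell over the same step. CCL26, MYL7, LHX4 and RASGRF2 had no count at Day 5 and were at least 104-, 65.8-, 63.3- and 61.7-fold lower than in hESC. ANXA3, with 3 counts at Day 5, fell 378-fold (counting interval 129 to 1841). TDGF1P3, a pseudogene that may share reads with the Nodal co-receptor gene TDGF1, fell by 8.01 ± 0.41 on the log2 scale. The smooth muscle gene TAGLN fell from 2607 to 11.9 CPM (-7.78 ± 0.44) and the skeletal muscle actin ACTA1 from 147 to 0.772 CPM (-7.50 ± 0.32). The adjusted p of these 16 genes ranged from 5.89e-16 to 5.78e-06. In all, 5453 of 12215 tested genes passed at an adjusted p under 0.05, with 2801 higher and 2652 lower at Day 5.

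Gene lists fixed in advance moved with this step. The pluripotency list fell (median log2 fold change -2.57 over 21 tested members, 17 fell and 2 rose over all genes, 18 fell and 2 rose adjusted over the list alone, camera adjusted p = 1.31e-26). POU5F1 stood at -3.92 ± 0.16, TDGF1 at -6.33 ± 0.28, LEFTY1 at -6.53 ± 0.32 and the DNA methyltransferase DNMT3B at -3.06 ± 0.16. POU5F1 shares sequence with POU5F1B and other copies, so its counts are uncertain. The actomyosin list fell too (median -0.81 over 47 members, 29 fell and 6 rose, 29 and 6 adjusted over the list alone, adjusted p = 1.04e-10). The forebrain list rose (median 3.61 over 20 members, 14 rose and 2 fell, 15 and 2 adjusted over the list alone, adjusted p = 5.37e-12). NR2F1 stood at 5.71 ± 0.24. The WNT list rose (25 rose and 7 fell of 39, 27 and 8 adjusted over the list alone, median 2.85, or 2.23 with members at 0 in hESC set at their bound, adjusted p = 6.32e-09). The ligand transporter WLS stood at 5.33 ± 0.27 and LEF1 at 5.72 ± 0.38. The choroid plexus, roof plate and cortical hem list rose (11 rose and 1 fell of 17, 12 and 1 adjusted over the list alone, median 4.10, or 3.40 at the bound, adjusted p = 5.53e-06). The radial glia list rose (10 rose and 1 fell of 13, also adjusted over the list alone, median 1.59, adjusted p = 1.07e-05). TTYH1 stood at 4.41 ± 0.20. The FGF, Notch and hedgehog list rose (16 rose and 8 fell of 30, 17 and 8 adjusted over the list alone, median 0.60, adjusted p = 0.0108). GAS1 stood at 4.01 ± 0.22. These 7 lists also passed with an estimated correlation.

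A further 5 lists passed with the preset correlation and not with an estimated one. The neural progenitor list rose (19 rose and 3 fell of 24, 20 and 3 adjusted over the list alone, median 2.13, adjusted p = 1.99e-08, and adjusted p = 0.0557 with an estimated correlation). DLK1 stood at 5.47 ± 0.27 and HES4 at 5.50 ± 0.39. The midbrain and hindbrain list rose (9 rose and 1 fell of 13, also adjusted over the list alone, median 3.20, adjusted p = 0.00244, and adjusted p = 0.275 with an estimated correlation). GBX2 stood at 3.20 ± 0.40. The surface ectoderm and epithelium list fell (10 fell and 1 rose of 12, also adjusted over the list alone, median -2.31, adjusted p = 6.15e-07, and adjusted p = 0.0564 with an estimated correlation), through the epithelial adhesion genes CDH1 (-4.68 ± 0.34) and EPCAM (-5.33 ± 0.37), which stem cells also express. The mesenchyme list fell (10 fell of 12, 11 adjusted over the list alone, median -2.78, adjusted p = 6.51e-07, and adjusted p = 0.169 with an estimated correlation). COL1A1 stood at -5.10 ± 0.38. The unfolded protein and heat shock list fell (13 fell and 4 rose of 25, 14 and 4 adjusted over the list alone, median -0.56, adjusted p = 0.0161, and adjusted p = 0.17 with an estimated correlation). The stress kinase-like gene TRIB3 stood at -2.96 ± 0.28. In LIS1+/-, the same step gave 5341 genes, 2733 higher and 2608 lower.

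From Day 5 to Day 12 in LIS1+/+, TTR, a transport protein of choroid plexus and liver, went from no count to 52.5 ± 71.3 CPM (at least 212-fold), and the collagen COL8A2 from no count to 10.8 ± 10.8 CPM (at least 44.3-fold). The fetal liver and yolk sac gene AFP rose by a log2 fold change of 6.90 ± 1.32, the collagen COL3A1 by 6.72 ± 0.91 and the neuropeptide gene SST by 6.62 ± 0.88. Levels of AFP and COL3A1 differed widely between the Day 12 LIS1+/+ libraries, as given below for the genotypes. TLX3 and DRC1, each with 2 counts at Day 5, rose 128-fold (counting interval 34.5 to 1070) and 114-fold (30.7 to 956). The remaining transcripts of the stem cell state fell further. POU5F1, with 3 counts at Day 12, was 59.3-fold lower (20.2 to 289) and TDGF1, with 2, was 41.9-fold lower (11.4 to 348). The log2 fold change was -4.70 ± 0.40 in POU5F1B, -4.65 ± 0.36 in VRTN, -4.53 ± 0.50 in ZSCAN10, -4.45 ± 0.47 in VSNL1 and -4.36 ± 0.48 in ESRG. SCGB3A2, with 3 counts, was 19.4-fold lower (6.51 to 95.2). Of 12215 tested genes 2990 passed, 1556 higher and 1434 lower, and adjusted p for the 16 genes taken by the rule ranged from 1.36e-11 to 0.0411. The highest was that of TTR, whose call was lost without Day 5 LIS1+/+ replicate 1, 2 or 3, without Day 12 LIS1+/+ replicate 3, in a fit of the compared libraries alone, without the 3 libraries that stood apart and with the GC trend removed (adjusted p up to 0.121).

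The lists showed neurogenesis genes rising and replication genes falling over this second step. The neurogenesis list rose (12 rose of 18, 13 adjusted over the list alone, median 1.90, adjusted p = 1.43e-10). HES6 stood at 1.87 ± 0.19, NEUROG1 at 4.39 ± 0.44 and the RNA-binding protein gene ELAVL3 at 3.25 ± 0.34. The hypoxia and glycolysis list rose (20 rose of 29, 21 adjusted over the list alone, median 1.26, adjusted p = 7.54e-15). BNIP3 stood at 2.80 ± 0.20 and VEGFA at 2.04 ± 0.21. The choroid plexus, roof plate and cortical hem list rose (11 rose and 2 fell of 17, also adjusted over the list alone, median 1.65, adjusted p = 7.97e-05). RSPO1 stood at 2.20 ± 0.25. The DNA replication list fell (16 fell of 30, 19 adjusted over the list alone, median -0.50, adjusted p = 3.39e-08). MCM5 stood at -1.38 ± 0.18, and the pluripotency list fell again (15 fell of 21, 16 adjusted over the list alone, median -2.15, or -1.99 at the bound, adjusted p = 2.68e-20). These 5 lists also passed with an estimated correlation. A further 4 rose with the preset correlation alone: collagens and matrix (21 rose and 7 fell of 45, 22 and 8 adjusted over the list alone, median 0.47, adjusted p = 0.000468, and adjusted p = 0.0745 with an estimated correlation), forebrain identity (10 rose and 1 fell of 20, 12 and 3 adjusted over the list alone, median 0.89, adjusted p = 0.000468, and adjusted p = 0.302 with an estimated correlation), mesenchyme (9 rose and 1 fell of 12, 9 and 2 adjusted over the list alone, median 2.17, adjusted p = 8.63e-05, and adjusted p = 0.318 with an estimated correlation) and neural crest (11 rose of 18, 12 adjusted over the list alone, median 1.45, adjusted p = 0.000385, and adjusted p = 0.327 with an estimated correlation). The Day 12 LIS1+/+ libraries differed widely in the last 2 of these lists. Median CPM in replicates 1, 2 and 3 was 43.9, 13.5 and 28.0 for mesenchyme and 36.8, 6.92 and 18.5 for neural crest. In LIS1+/- this step gave 2020 genes, 1087 higher and 933 lower, and 1317 without Day 12 LIS1+/- replicate 2.

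The main question of the design was what the LIS1+/- genotype changed at each stage. In hESC, the HES-family gene HES4 was 5.44-fold higher in LIS1+/- (72.7 ± 19.7 against 13.7 ± 7.38 CPM, SD, n = 3 each, adjusted p = 0.00526). CDKN2A, which encodes inhibitors of the cell cycle, was 3.20-fold higher (237 ± 5.51 against 74.1 ± 7.42 CPM, adjusted p = 0.000579). The muscle actin gene ACTA1 was 3.10-fold higher (log2 fold change 1.63 ± 0.19, adjusted p = 7.48e-05) and the protocadherin gene PCDHB2 3.47-fold higher (adjusted p = 0.00225). Among the genes that fell, the imprinted non-coding RNA MEG3 was 6.77-fold lower (3.79 ± 3.07 against 26.4 ± 10.7 CPM, adjusted p = 0.00758). The kinase gene PIM2 was 2.67-fold lower (adjusted p = 0.000579), the RNA polymerase III subunit gene POLR3K 2.50-fold lower (adjusted p = 0.000658) and the DNA polymerase epsilon subunit gene POLE4 2.10-fold lower (adjusted p = 0.00308).

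The other hESC genes named by the rule were higher by 3.01- to 3.82-fold (PDGFB, LRRC4B, STOML3, ADGRG1, ZNF667 and GDPD5) or lower by 2.12- to 4.31-fold (KCNK12, SYT11, LGALS1, ARRB1, TNFRSF10B and PIN4), with adjusted p from 0.00991 to 0.0394. Across the 12215 tested genes 60 passed, 36 higher and 24 lower, of which 27 and 15 differed at least 2-fold. Of the 20 named genes, HES4, PCDHB2, CDKN2A, ACTA1, PIM2, POLR3K and POLE4 passed with each of the 6 hESC libraries left out in turn, while 13 lost the call with at least 1 of them: 12 without LIS1+/+ replicate 1 (MEG3 among them, adjusted p = 0.0597), 7 without LIS1+/+ replicate 2, 9 without LIS1+/+ replicate 3, and 7, 11 and 9 without LIS1+/- replicates 1, 2 and 3. Of the 8 called genes named as list members, 6 lost the call with at least 1 library left out: 6, 4 and 5 without LIS1+/+ replicates 1, 2 and 3 and 3, 5 and 5 without LIS1+/- replicates 1, 2 and 3 (adjusted p up to 0.328). The count of genes itself was 21, 35 and 30 without LIS1+/+ replicates 1, 2 and 3 and 22 and 21 without LIS1+/- replicates 2 and 3, but 153 in a fit of the hESC libraries alone, 139 with DESeq2, 206 with no filter on low counts and 110 with the trend in GC content removed.

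The stem cell lists shifted by small amounts in hESC. The pluripotency list fell (median -0.33 over 21 members, none passed over all genes and 5 fell adjusted over the list alone, adjusted p = 0.000143, and adjusted p = 0.025 with an estimated correlation). DNMT3B stood at -0.42 and TDGF1 at -0.67. The DNA replication list fell (median -0.22 over 30 members, none passed over all genes and 2 fell adjusted over the list alone, adjusted p = 0.000223, and adjusted p = 0.0217 with an estimated correlation). The collagens and matrix list rose (median 0.36 over 45 members, 4 rose, 10 adjusted over the list alone, adjusted p = 2.47e-07, and adjusted p = 0.0214 with an estimated correlation). COL2A1 stood at 1.34 ± 0.24 and CYR61 at 0.95 ± 0.21. The actomyosin list rose (median 0.28 over 47 members, 2 rose, and 10 rose and 2 fell adjusted over the list alone, adjusted p = 1.38e-05, and adjusted p = 0.00282 with an estimated correlation) through ACTA1 and the filamin gene FLNC (1.01 ± 0.18). The immediate early list rose (median 0.37 over 19 members, none passed over all genes and 4 rose adjusted over the list alone, adjusted p = 0.000223, and adjusted p = 0.025 with an estimated correlation). JUN stood at 0.87 (adjusted p = 0.0587). The neural progenitor list rose (median 0.43 over 24 members, 3 rose, 4 adjusted over the list alone, adjusted p = 0.000513, and adjusted p = 0.367 with an estimated correlation) through HES4, DLK1 (1.32 ± 0.24) and the eye-field and forebrain gene SIX3 (1.05 ± 0.22), and with fry the call was lost (adjusted p = 0.0918). With the 6 hESC libraries left out in turn, the calls of SIX3 and CYR61 were each lost 6 times and that of DLK1 5 times (adjusted p up to 0.138, 0.178 and 0.062). The ribosomal protein list fell (median -0.09 over 46 members, none passed, adjusted p = 0.0134, and adjusted p = 0.692 with an estimated correlation), a call that was lost without LIS1+/+ replicate 1 (adjusted p = 0.203) and without LIS1+/- replicates 2 (0.243) and 3 (0.5), with medians of -0.05, -0.06 and -0.01, and with fry (0.502). Its median was -0.23 without LIS1+/- replicate 1, and that of the immediate early list was 0.56 without LIS1+/+ replicate 1. Both genotypes of hESC had the high shares of not unique alignments given above, and these differed between the genotypes.

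At Day 5, genes of the stem cell state were lower in LIS1+/- organoids. POU5F1 stood at 7.25 ± 1.37 against 34.2 ± 2.78 CPM (4.74-fold lower, adjusted p = 4.18e-08), the surface protein gene PODXL at 60.9 ± 1.96 against 248 ± 32.7 CPM (4.07-fold lower, adjusted p = 2.06e-08), and L1TD1, an RNA-binding protein gene of embryonic stem cells, at 3.32 ± 2.96 against 30.2 ± 7.48 CPM (9.32-fold lower, adjusted p = 3.5e-05). The ligand gene NODAL was 11.7-fold lower (adjusted p = 0.000229), the co-receptor gene TDGF1 7.26-fold (adjusted p = 0.00015) and the transcription factor gene FOXH1 11.9-fold (adjusted p = 0.000636), while the list of BMP, TGF-beta and activin signalling did not pass (median -0.18, adjusted p = 0.402). MIXL1, a gene of the primitive streak, was 32.9-fold lower (0.661 ± 0.259 against 23.7 ± 16.5 CPM, adjusted p = 8.86e-05). TCEAL5, with 2 counts in LIS1+/-, was 115-fold lower (counting interval 31.7 to 956, adjusted p = 1.62e-06).

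SIX6, VAX2 and ALDH1A3 were among the genes higher at Day 5. SIX6, a gene of the eye field, stood at 101 ± 23.5 against 18.3 ± 3.47 CPM (5.48-fold, adjusted p = 0.0206), VAX2 at 42.3 against 6.35 CPM (6.63-fold, log2 fold change 2.73 ± 0.44, adjusted p = 0.000631), and ALDH1A3, a retinoic acid synthesis gene of the optic vesicle, at 17.1 ± 3.00 against 2.15 ± 0.701 CPM (7.81-fold, adjusted p = 0.000366). CDKN2A was 5.76-fold higher (adjusted p = 2.15e-06) and the steroid dehydrogenase gene HSD17B2 11.7-fold higher (adjusted p = 0.000125). MAB21L1, ATP6V1B1, PLK2, CLDN1 and ADAMTS18 were 4.22- to 6.78-fold higher (adjusted p from 0.0015 to 0.00812). On the other side, SCGB3A2, ESRG, MEG3, ZSCAN10 and RARRES2 were 8.42- to 22.3-fold lower (adjusted p from 3.5e-05 to 0.00253).

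In all, 238 of the 12215 genes passed at Day 5, 82 higher and 156 lower in LIS1+/-, of which 63 and 121 differed at least 2-fold. The count was 126, 125 and 138 without LIS1+/+ replicates 1, 2 and 3, 154 and 128 without LIS1+/- replicates 1 and 3, and 412 with no filter on low counts. Of the 20 genes named by size of change, 18 passed with each of the 6 libraries left out in turn. The exceptions were SIX6, which passed only without LIS1+/- replicate 2 and reached an adjusted p of 0.102 without LIS1+/+ replicate 3, and ADAMTS18, which missed the threshold without LIS1+/+ replicate 1 or 2 (adjusted p up to 0.0615). Of the 42 called genes named as list members, 25 lost the call with at least 1 library left out: 22, 18 and 15 without LIS1+/+ replicates 1, 2 and 3 and 14, 13 and 19 without LIS1+/- replicates 1, 2 and 3 (adjusted p up to 0.327).

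**Figure D2:**
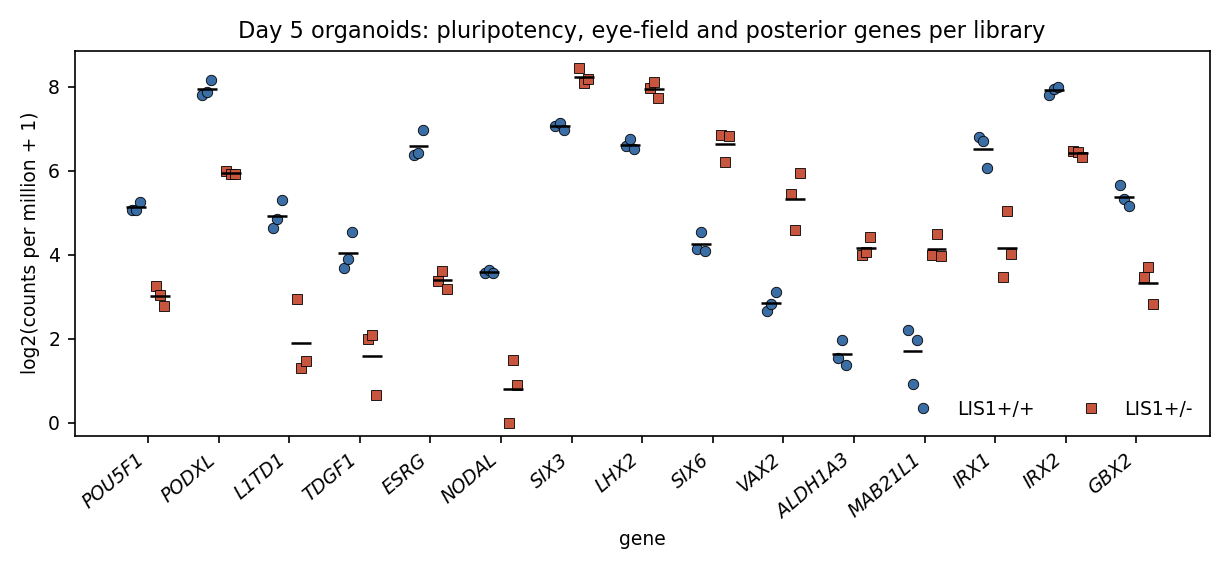
Level at Day 5 of genes of the stem cell state, the anterior neural plate and eye field, and more posterior regions, as log2 of CPM plus 1 (vertical axis), with a point for each library, circles for LIS1+/+, squares for LIS1+/- and a line at each mean of the logs. POU5F1, PODXL, IRX1, IRX2 and GBX2 lie lower in LIS1+/-, and SIX3, LHX2, SIX6, VAX2 and ALDH1A3 higher, with no overlap between the libraries of the 2 genotypes.

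The Day 5 lists followed these genes. The pluripotency list fell (median -2.02 over 21 members, or -1.96 with members at 0 in 1 group set at their bound, 8 fell over all genes, and 16 fell and 1 rose adjusted over the list alone, adjusted p = 6.22e-35, and adjusted p = 1.21e-05 with an estimated correlation), and DNMT3B fell by 0.90 ± 0.15. The pluripotency median was -1.14 without LIS1+/+ replicate 3 and -0.80 in a fit of the Day 5 libraries alone, and the list passed in both. No other Day 5 list passed with an estimated correlation. With the preset correlation the forebrain list rose (median 0.27 over 20 members, 5 rose, 6 adjusted over the list alone, adjusted p = 0.000442, and adjusted p = 0.307 with an estimated correlation). SIX3 stood at 1.19 ± 0.20 (303 against 133 CPM), NR2F1 at 0.95 ± 0.17 and LHX2 at 1.34 ± 0.28. The midbrain and hindbrain list fell (median -0.76 over 13 members, or -0.45 at the bound, 4 fell, 5 adjusted over the list alone, adjusted p = 4.53e-06, and adjusted p = 0.249 with an estimated correlation). GBX2 stood at -2.14 ± 0.33, IRX1 at -2.30 ± 0.35 and IRX2 at -1.51 ± 0.24. The mesoderm and endoderm list fell (median -1.70 over 11 members, 2 fell, 4 adjusted over the list alone, adjusted p = 7.03e-05, and adjusted p = 0.116 with an estimated correlation) through MIXL1 and EOMES, which had 2 counts in LIS1+/- and was 26.4-fold lower (counting interval 7.08 to 222). The surface ectoderm and epithelium list fell (median -1.10 over 12 members, 2 fell, 3 adjusted over the list alone, adjusted p = 0.00105, and adjusted p = 0.307 with an estimated correlation, adjusted p = 0.0653 without LIS1+/- replicate 3) through KRT18 (-0.98 ± 0.22) and CDH1 (-2.68 ± 0.60), both also expressed by stem cells. The median of the mesoderm and endoderm list was -0.94 without LIS1+/+ replicate 3, and that of the midbrain and hindbrain list -1.43 and -0.42 without LIS1+/- replicates 2 and 3. With fry the forebrain (adjusted p = 0.128) and surface ectoderm (0.0649) calls were lost. With the 6 libraries left out in turn, the calls of LHX2, EOMES and CDH1 were each lost 3 times and that of KRT18 4 times (adjusted p up to 0.0983).

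The hypoxia and glycolysis list fell at Day 5 (median -0.29 over 29 members, 3 fell, 5 adjusted over the list alone, adjusted p = 0.000152, and adjusted p = 0.307 with an estimated correlation), through the glucose transporters SLC2A3 (-1.35 ± 0.20) and SLC2A1 (-0.68 ± 0.15) and the glycolytic enzyme gene ALDOC (-1.38 ± 0.35). The FGF, Notch and hedgehog list fell (median -0.24 over 30 members, 3 fell and 1 rose, 7 and 2 adjusted over the list alone, adjusted p = 0.0199, and adjusted p = 0.116 with an estimated correlation). ETV4 stood at -1.22 ± 0.27 and GAS1 at 0.87 ± 0.16. The call was lost without LIS1+/+ replicate 3 (adjusted p = 0.0503) and without LIS1+/- replicates 1 (0.133) and 3 (0.0723). The radial glia list fell (median -0.42 over 13 members, 1 fell, 2 fell and 1 rose adjusted over the list alone, adjusted p = 0.0302, and adjusted p = 0.307 with an estimated correlation). NOTCH1, its 1 called member, stood at -0.68 ± 0.18. The radial glia call was lost without LIS1+/+ replicate 3 (adjusted p = 0.0986) or LIS1+/- replicate 1 (0.132). The mesenchyme list fell (median -0.44 over 12 members, 1 fell, 1 adjusted over the list alone, adjusted p = 0.0336, and adjusted p = 0.722 with an estimated correlation). COL1A2, its 1 called member, stood at -1.51 ± 0.38. The list call was lost without LIS1+/+ replicate 3 (adjusted p = 0.154) and without LIS1+/- replicates 2 (0.189) and 3 (0.0943). The mesenchyme call was also lost with no filter (0.202), with fry (0.41), without the 3 libraries that stood apart (0.239) and with the GC trend removed (0.0518), and the hypoxia call with fry (0.0649). Without 1 library the median was -0.13 for the FGF, Notch and hedgehog list (LIS1+/- replicate 1) and -0.28 for mesenchyme (LIS1+/- replicate 2). With the 6 libraries left out in turn, the calls of SLC2A1 and ETV4 were each lost 3 times, those of ALDOC and NOTCH1 5 times and that of COL1A2 6 times (adjusted p up to 0.236).

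At Day 12, markers of neural crest and mesenchyme were lower in LIS1+/-. SOX10, a regulator of neural crest, stood at 1.28 ± 0.655 against 43.2 ± 41.6 CPM (35.2-fold lower, SD, n = 3 each, adjusted p = 0.00369). TWIST1, a regulator of mesenchyme, stood at 3.55 ± 1.34 against 94.9 ± 94.2 CPM (28.2-fold lower, adjusted p = 0.00104), COL3A1 at 3.85 ± 1.49 against 94.1 ± 97.4 CPM (26.0-fold lower, adjusted p = 0.00642) and TFAP2A at 2.22 ± 0.859 against 47.5 ± 39.7 CPM (19.5-fold lower, adjusted p = 0.0045). GATA3, with 3 counts in LIS1+/-, was 26.6-fold lower (counting interval 8.58 to 134, adjusted p = 0.0104), and TCEAL5, also with 3, was 71.6-fold lower (23.9 to 352, adjusted p = 2.08e-05). AFP, the endothelin gene EDN3 and MEG3 were 57.3-, 21.5- and 27.2-fold lower (adjusted p of 0.0377, 0.00583 and 0.000193). The 3 LIS1+/+ libraries differed widely in these genes, as their SDs show. Without LIS1+/+ replicate 1 the log2 fold change went from -5.84 to -2.88 in AFP, from -4.42 to -3.01 in EDN3 (adjusted p = 0.139), from -5.14 to -4.12 in SOX10, from -4.82 to -3.69 in TWIST1, from -4.70 to -3.49 in COL3A1 and from -4.29 to -3.41 in TFAP2A. The call of AFP was lost without LIS1+/- replicates 1, 2 or 3 (adjusted p of 0.0847, 0.126 and 0.181), and that of GATA3 without LIS1+/+ replicate 1 (0.267) or LIS1+/- replicates 1, 2 or 3 (0.0512, 0.0735 and 0.0603). That of COL3A1 was lost without LIS1+/- replicates 2 (0.0563) or 3 (0.0741), and that of EDN3 also without LIS1+/- replicate 3 (0.0527).

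Genes that were higher at Day 12 changed by less. CDKN2A was 16.7-fold higher (16.5 ± 3.04 against 1.01 ± 0.456 CPM, adjusted p = 4.14e-05). WNT8B, of the cortical hem, stood at 220 ± 37.8 against 82.8 ± 25.4 CPM (2.64-fold, adjusted p = 0.00233), and the adhesion gene IGSF21 was 3.32-fold higher (adjusted p = 0.00073). ZNF667-AS1 was 2.69-fold and ZNF667, on the opposite strand, 2.89-fold higher (adjusted p of 0.000258 and 0.00888), and counts of the pair may be shared. CCNO, the synaptic gene NLGN1, BAIAP3, FBXO41 and MAPK8IP2 were 2.66- to 7.05-fold higher (adjusted p from 0.00866 to 0.0252). In all, 171 genes passed at Day 12, 41 higher and 130 lower, of which 22 and 106 differed at least 2-fold.

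The Day 12 result moved with single libraries. The count was 93, 271 and 332 without LIS1+/+ replicates 1, 2 and 3, 97, 83 and 57 without LIS1+/- replicates 1, 2 and 3, 41 in a fit of the Day 12 libraries alone, 290 with DESeq2, 483 with no filter and 381 without the 3 libraries that stood apart. Of the 20 named genes, CDKN2A, IGSF21, ZNF667-AS1, WNT8B, TCEAL5, SOX10, TWIST1, MEG3 and TFAP2A passed with each library left out in turn, while 6, 1 and 4 lost the call without LIS1+/+ replicates 1, 2 and 3 and 7, 7 and 10 without LIS1+/- replicates 1, 2 and 3 (adjusted p up to 0.267). Of the 34 called genes named as list members, 22 lost the call with at least 1 library left out: 15, 5 and 2 without LIS1+/+ replicates 1, 2 and 3 and 14, 16 and 18 without LIS1+/- replicates 1, 2 and 3 (adjusted p up to 0.323). In the fit of the Day 12 libraries alone SOX10, TWIST1, COL3A1 and EDN3 were among the genes that no longer passed.

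**Figure D3:**
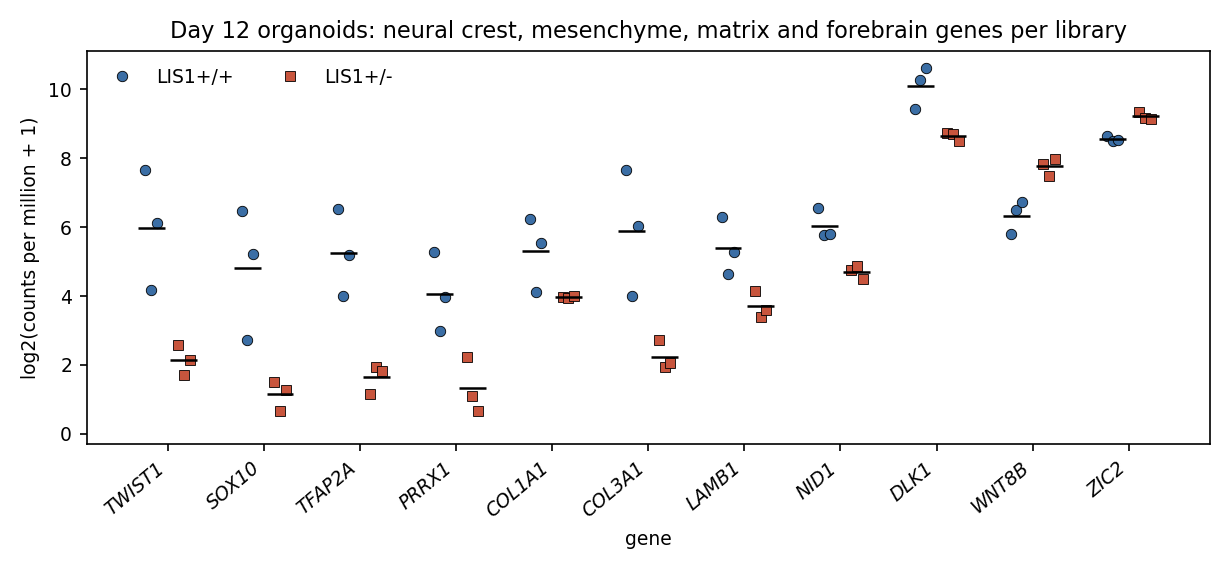
Level at Day 12 of neural crest, mesenchyme, matrix and forebrain genes, as log2 of CPM plus 1 (vertical axis), with a point for each library, circles for LIS1+/+, squares for LIS1+/- and a line at each mean of the logs. The 3 LIS1+/+ libraries are spread widely in TWIST1, SOX10, TFAP2A and COL3A1, and WNT8B and ZIC2 lie higher in LIS1+/-.

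With the preset correlation 12 lists passed at Day 12, and with an estimated correlation none did (fry, which asks whether members move 1 way on balance, called 15). The neural crest list fell (median -1.84 over 18 members, 9 fell, 11 adjusted over the list alone, adjusted p = 3.01e-14, and adjusted p = 0.108 with an estimated correlation). The mesenchyme list, which shares TWIST1 with it, fell (median -1.31 over 12 members, 6 fell, 9 adjusted over the list alone, adjusted p = 2.34e-10, and adjusted p = 0.135 with an estimated correlation). PRRX1 stood at -3.66 ± 0.72, a call lost without LIS1+/+ replicate 1 (-2.81, adjusted p = 0.102) or LIS1+/- replicates 2 (0.0678) or 3 (0.0843). Over the 29 genes of both lists the median was -1.62, and -0.87 without LIS1+/+ replicate 1. The collagens and matrix list fell (median -0.32 over 45 members, 8 fell, 11 adjusted over the list alone, adjusted p = 6.89e-06, and adjusted p = 0.0778 with an estimated correlation). The basement membrane genes NID1 stood at -1.41 ± 0.22 and LAMB1 at -1.95 ± 0.32. The surface ectoderm and epithelium list fell (median -2.26 over 12 members, or -2.01 at the bound, 4 fell, and 8 fell and 1 rose adjusted over the list alone, adjusted p = 6.89e-06, and adjusted p = 0.149 with an estimated correlation) through TFAP2A, which is also on the neural crest list, GATA3, EPCAM (-1.87 ± 0.44) and CDH1, which had no count in LIS1+/-. The mesoderm and endoderm list fell (median -1.99 over 11 members, 2 fell, 5 adjusted over the list alone, adjusted p = 0.00262, and adjusted p = 0.174 with an estimated correlation) through AFP and APOA1 (-3.51 ± 0.77), both liver and yolk sac genes. The calls of APOA1, EPCAM and CDH1 were each lost without LIS1+/+ replicate 1 or LIS1+/- replicates 1, 2 or 3 (adjusted p up to 0.171, 0.224 and 0.323). Without LIS1+/+ replicate 1 APOA1 stood at -1.95 and EPCAM at -1.07.

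The pluripotency list fell at Day 12 (median -0.59 over 21 members, or -0.16 at the bound, 3 fell, 5 adjusted over the list alone, adjusted p = 0.00013, and adjusted p = 0.0778 with an estimated correlation). PODXL stood at -0.85 ± 0.18 and LIN28A at -0.92 ± 0.24. The first lost its call without LIS1+/+ replicate 3 or LIS1+/- replicates 1 or 2 (adjusted p up to 0.0709), and the second in these settings and without LIS1+/+ replicate 1 (up to 0.323). The hypoxia and glycolysis list fell (median -0.37 over 29 members, 1 fell, 4 adjusted over the list alone, adjusted p = 1.81e-05, and adjusted p = 0.185 with an estimated correlation), with SLC2A3 (-1.30 ± 0.20) its called member. The ribosomal protein list fell (median -0.26 over 46 members, 1 fell, 10 adjusted over the list alone, adjusted p = 3.69e-08, and adjusted p = 0.185 with an estimated correlation). RPL22, its 1 called member, stood at -0.68 ± 0.16 and passed only without LIS1+/+ replicate 3 when the 6 libraries were left out in turn (adjusted p up to 0.175 in the others). The retinoic acid list fell (median -0.95 over 12 members, 1 fell, 2 adjusted over the list alone, adjusted p = 0.000587, and adjusted p = 0.135 with an estimated correlation). ALDH1A3 (-2.70 ± 0.57), its called member, lost its call without LIS1+/+ replicate 2 (adjusted p = 0.0773) or LIS1+/- replicate 2 (0.0588). The median of the list was -0.42 in a fit of the Day 12 libraries alone, where the call was lost (adjusted p = 0.0969), and -0.10 with no filter. The BMP, TGF-beta and activin list fell (median -0.21 over 28 members, 2 fell, 5 adjusted over the list alone, adjusted p = 0.0387, and adjusted p = 0.293 with an estimated correlation). The activin antagonist FST stood at -1.61 ± 0.23. The call was lost without LIS1+/+ replicate 1 (adjusted p = 0.261, where the median was 0.01), without LIS1+/- replicates 2 (0.109) and 3 (0.116), with no filter (0.107), in a fit of the Day 12 libraries alone (0.116), with fry (0.124) and with the GC trend removed (0.161). The imprinted list fell (median -0.17 over 21 members, 2 fell, also adjusted over the list alone, adjusted p = 0.0495, and adjusted p = 0.135 with an estimated correlation) through MEG3 and DLK1 (401 against 1168 CPM, -1.54 ± 0.23). The call was lost without LIS1+/+ replicates 2 (adjusted p = 0.0618) and 3 (0.139) and without LIS1+/- replicates 1 (0.0947), 2 (0.0599) and 3 (0.116), with no filter (0.191), in a fit of the Day 12 libraries alone (0.066), with the replicate number as a block (0.0518) and with the GC trend removed (0.176). The choroid plexus, roof plate and cortical hem list passed in the upward direction (median 0.32 but mean -0.02 over 17 members, 1 rose, and 6 rose and 3 fell adjusted over the list alone, adjusted p = 0.0495, and adjusted p = 0.216 with an estimated correlation), with WNT8B its called member. The call was lost without LIS1+/+ replicates 2 (adjusted p = 0.0896) and 3 (0.247), without LIS1+/- replicate 1 (0.157), with no filter (0.116), with the replicate number as a block (0.202), with fry (0.0986) and without the 3 libraries that stood apart (0.0533).

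Single libraries moved the Day 12 medians. Without LIS1+/+ replicate 1 they were -0.92 for the neural crest list, -0.83 for mesenchyme, -0.19 for collagens and matrix, -1.07 for surface ectoderm, -1.31 for mesoderm and endoderm, -0.06 for pluripotency, -0.21 for hypoxia, -0.27 for retinoic acid, -0.09 for imprinted genes and 0.62 for choroid plexus. Without LIS1+/+ replicate 2 they were -3.70 for mesoderm and endoderm, -1.99 for mesenchyme and -0.03 for imprinted genes. Without LIS1+/- replicate 2 they were -3.15 for mesoderm and endoderm, -0.28 for pluripotency and -0.13 for the BMP list, and without LIS1+/- replicate 3 -3.18 for mesoderm and endoderm and -0.21 for hypoxia. The surface ectoderm call was lost in a fit of the Day 12 libraries alone (median -1.35, adjusted p = 0.0589).

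**Figure D4:**
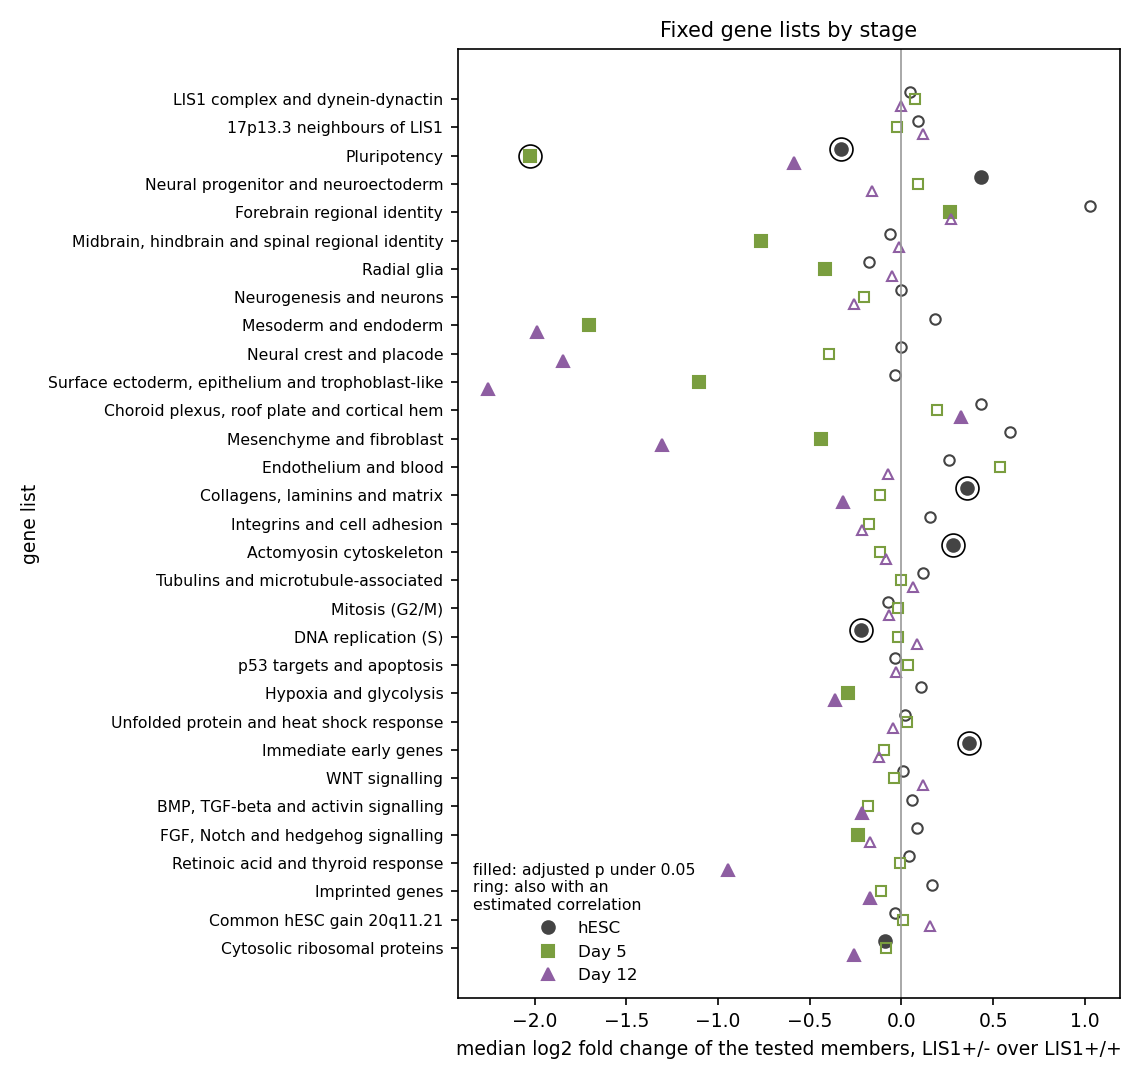
Median log2 fold change of LIS1+/- over LIS1+/+ (horizontal axis) over the tested members of each of the 31 gene lists, with a symbol for each stage, filled where camera passed with the preset correlation and ringed where it also passed with an estimated one. The pluripotency list lies at -0.33, -2.02 and -0.59, and the neural crest list at -1.84 at Day 12.

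Several lists passed in no genotype comparison. For the LIS1 complex and dynein-dynactin genes the medians were 0.04, 0.08 and 0.00 in hESC, at Day 5 and at Day 12 (adjusted p of 0.982, 0.534 and 0.951), with PAFAH1B1 at Day 12 the 1 of 27 members that passed. For the neighbours of LIS1 in 17p13.3 they were 0.09, -0.03 and 0.12 (adjusted p of 0.502, 0.765 and 0.17), with none of 28 members called. The mitosis list had medians of -0.08, -0.02 and -0.07 (adjusted p of 0.448, 0.781 and 0.951), and the tubulin list 0.12, 0.00 and 0.07 (adjusted p of 0.241, 0.781 and 0.0872). The p53 list had medians of -0.04, 0.03 and -0.03 (adjusted p of 0.497, 0.781 and 0.794), the neurogenesis list 0.00, -0.20 and -0.26 (0.497, 0.17 and 0.268), the integrin and adhesion list 0.15, -0.18 and -0.22 (0.274, 0.541 and 0.223), the unfolded protein list 0.02, 0.03 and -0.05 (0.925, 0.532 and 0.169) and the WNT list 0.01, -0.04 and 0.12 (0.733, 0.781 and 0.534). The genes of 20q11.21, a segment often gained in stem cell cultures, had medians of -0.04, 0.01 and 0.15 (0.497, 0.482 and 0.254), and the endothelium and blood list, with 5 tested members, 0.26, 0.54 and -0.07 (0.497, 0.541 and 0.478).

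Some genes differed between the genotypes at all 3 stages in the same direction. CDKN2A and PCDHB2 were higher and MEG3, PIN4, POLE4, POLR3K, TCEAL5 and TNFRSF10B were lower, 8 genes in all where independent lists would give 0.000811 higher and 0.00326 lower. The lists are not fully independent, because the comparisons share 1 fit and its estimate of the spread of each gene. Across all tested genes the effects correlated at 0.080 (hESC and Day 5), 0.124 (hESC and Day 12) and 0.150 (Day 5 and Day 12). POLE4 fell from 164 to 78.7 CPM in hESC, from 150 to 74.1 CPM at Day 5 and from 109 to 59.5 CPM at Day 12. MEG3 fell from 26.4 to 3.79, from 43.5 to 4.91 and from 20.3 to 0.792 CPM. The log2 fold change of PCDHB2 was 1.80, 0.86 and 1.23, that of the RNA polymerase III gene POLR3K -1.32, -1.03 and -0.88, that of the prolyl isomerase gene PIN4 -1.08, -0.86 and -0.86, and that of the death receptor gene TNFRSF10B -1.13, -0.81 and -0.99. TCEAL5, which lies below the level set for named genes in hESC and is named after its values were seen, measured 6.80 ± 5.28 CPM in hESC LIS1+/+ and had no count in hESC LIS1+/-. Called genes of hESC and Day 5 shared 6 higher and 10 lower, those of hESC and Day 12 shared 5 and 9, and those of Day 5 and Day 12 shared 4 and 20. In the same pairs of stages 1, 3 and 9 genes were called in opposite directions. The count of 8 was 4 without hESC LIS1+/+ replicate 1, 5 without hESC LIS1+/- replicate 3, without Day 5 LIS1+/+ replicate 1 or 2, or without Day 5 LIS1+/- replicate 1 or 3, and 4, 3 and 4 without Day 12 LIS1+/- replicates 1, 2 and 3, in fits of each stage alone it was 2.

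**Figure D5:**
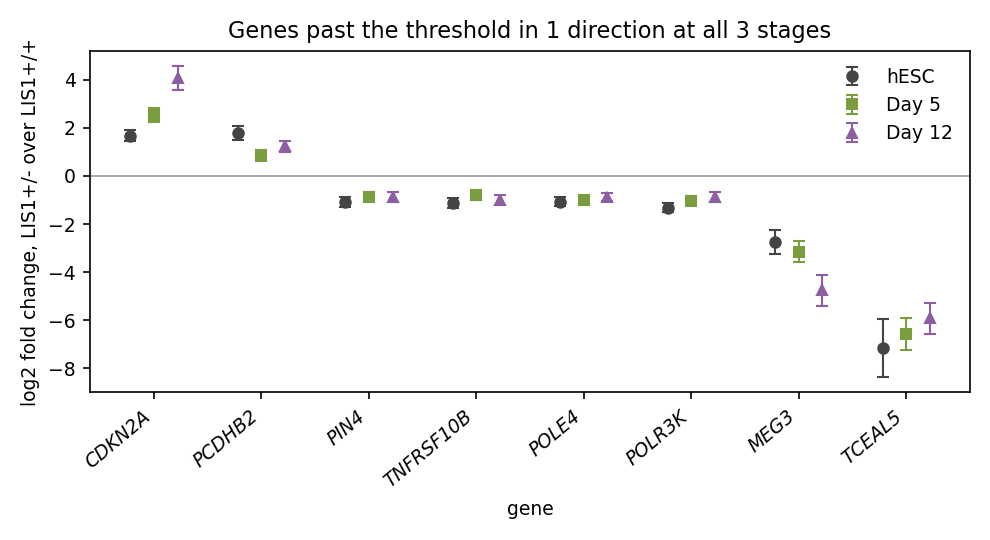
Fitted log2 fold change of LIS1+/- over LIS1+/+ (vertical axis) of the 8 genes past the threshold in 1 direction at all 3 stages, with a symbol for each stage and error bars of 1 SE. CDKN2A lies at 1.68, 2.53 and 4.06 and MEG3 at -2.76, -3.14 and -4.76, while the fitted values of TCEAL5, which had 0 to 3 counts in LIS1+/-, are no measure of its size of change.

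The genotype effect itself was compared between stages. It differed in 70 genes between Day 5 and hESC, 10 more positive and 60 more negative at Day 5, with POU5F1 at -2.06 and PODXL at -2.21 on the log2 scale for the difference. It differed in 129 genes between Day 12 and Day 5, 47 more positive and 82 more negative at Day 12, with the optic vesicle gene ALDH1A3 at -5.66 and ZIC2, a regulator of forebrain midline growth, at 1.41. Between Day 12 and hESC it differed in 46 genes, 2 more positive and 44 more negative, with DLK1 at -2.86 and NID1 at -2.04. The 70 fell to 31 without hESC LIS1+/+ replicate 3, the 129 to 59 without Day 12 LIS1+/- replicate 3 and the 46 to 11 without Day 12 LIS1+/- replicate 3, while the last rose to 138 without Day 12 LIS1+/+ replicate 2.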

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

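Of the tests in this part, those of leftover cells, of lists along the wild-type course and of other splits of the libraries, and the tests of lists for a difference between stages, were chosen only after the results were seen. Each result here differed between stages in its genotype effect by a test of the difference itself. The genes are those named by the rule, and of 398 other named genes 24, 37 and 20 passed for Day 5 minus hESC, Day 12 minus Day 5 and Day 12 minus hESC. Only lists that passed with both correlations are given.

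Between Day 5 and hESC the genotype effect differed in 70 genes, with values on the log2 scale of 1.30 for MDFI, 3.98 for ALDH1A3, 1.26 for GLIS2, 2.40 for ARRB1 and 1.12 for SFRP2. It was more negative at Day 5 by -2.21 in PODXL, -2.06 in POU5F1, -2.42 in POU5F1B, -4.64 in STOML3 and -1.60 in ASS1. The pluripotency list (adjusted p = 0.000935 with an estimated correlation) and the actomyosin list (adjusted p = 0.00713 with an estimated correlation) also differed. Of 100 splits of the libraries, 1, the real one, gave as many genes, and the highest of the others gave 47. That split kept the real grouping at Day 5. Splits that mix the genotypes put genotype differences into the spread, which lowers their counts, so the splits do not decide on chance. Without single libraries the count was 45, 31, 41 and 36 (hESC LIS1+/+ replicates 2 and 3, LIS1+/- replicates 2 and 3) and 39 and 38 (Day 5 LIS1+/+ replicates 1 and 2).

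Between Day 12 and Day 5 it differed in 129 genes, with 3.13 for CD9, 1.41 for ZIC2, 2.99 for FAM181B, 1.70 for DMKN and 1.398 for ASS1, and with -5.66 for ALDH1A3, -3.35 for MEIS2, -5.31 for MAB21L1, -4.80 for HSD17B2 and -4.02 for SPP1. Of 100 splits 1 gave as many, the real one, and the highest other gave 82, in a split that kept the real grouping at Day 5. For the reason given above, these splits do not decide on chance. The count was 75 and 79 without Day 5 LIS1+/+ replicates 1 and 2, and 84 and 59 without Day 12 LIS1+/- replicates 2 and 3.

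Between Day 12 and hESC it differed in 46 genes, with 0.96 for ZIC2, 1.14 for CD9, -1.94 for PKDCC, -2.86 for DLK1, -3.76 for SPP1, -1.87 for FLNC and -2.04 for NID1. The lists of collagens and matrix (adjusted p = 0.00128), actomyosin (adjusted p = 0.00971), DNA replication (adjusted p = 0.00845) and imprinted genes (adjusted p = 0.0299), all with an estimated correlation, differed too. Of 100 splits 1 gave as many, the real one, and the highest other gave 14, in a split that kept the real grouping at Day 12. Here too the splits do not decide on chance. The count was 24 and 24 without hESC LIS1+/+ replicates 1 and 3, 29 and 19 without hESC LIS1+/- replicates 1 and 3, 138 without Day 12 LIS1+/+ replicate 2, and 25, 28 and 11 without Day 12 LIS1+/- replicates 1, 2 and 3.

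The lower pluripotency genes of LIS1+/- at Day 5 were weighed against technical explanations. A library that stands apart in its GC trend is argued against, since the median was -2.26 without Day 5 LIS1+/- replicate 2 and -2.04 with the trend removed, against -2.02. It was -1.14 without Day 5 LIS1+/+ replicate 3 and -0.80 in a fit of the Day 5 libraries alone. Leftover cells in the state of the hESC cultures are argued against for 6 of the 8 called genes, DNMT3B, ESRG, L1TD1, NODAL, PODXL and POU5F1. Of 2260 abundant hESC genes, 3 outside the pluripotency list allow at most 0.922% of such cells at Day 5 in LIS1+/+, among them TAGLN (2607 CPM in hESC LIS1+/+ and 11.9 CPM at Day 5) and ACTA1 (147 and 0.772 CPM), named after their values were seen. For their loss from LIS1+/+ to LIS1+/- the 6 genes need at least 2.66%, with both limits taken from the libraries most favourable to leftover cells. For LEFTY1 and TDGF1, which need as little as 0.112%, it stays open, as do cells that kept pluripotency genes and had lost the others.

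Whether LIS1+/- organoids may be further along the wild-type course at Day 5 stays open. Genes that rose from hESC to Day 12 had a median effect 0.229 above that of genes that fell, against at most 0.201 in the 9 other splits of these libraries, a narrow margin. From the fit the medians were 0.103 and -0.120. The criterion set for this reading before the test was thereby met, though narrowly. Of 11 lists that rose in LIS1+/+ in at least 1 of the steps from hESC to Day 5 and from Day 5 to Day 12 and passed as falling in neither, 1 passed as higher at Day 5 in LIS1+/- (forebrain) and 4 passed as lower. These 4 were midbrain and hindbrain (median -0.76), radial glia (-0.42), hypoxia and glycolysis (-0.29) and FGF, Notch and hedgehog (-0.24). Each goes against this reading only for the step in which it rose. The hypoxia list rose only from Day 5 to Day 12 (median 1.26), after a median of -0.46 in the first step (adjusted p = 0.0875), so it bears on the second step alone. The midbrain and hindbrain, radial glia and FGF, Notch and hedgehog lists passed as rising only in the first step. Their camera adjusted p in the second were 0.786, 0.562 and 0.15, so they bear on the first alone. The collagens and matrix list, also among the 11, had a median of -0.24 in the first step. Of 5 lists that fell by the same reckoning, 2 passed as lower and 0 as higher. These calls are with the preset correlation, and of the 7 only the pluripotency list also passed with an estimated one. The radial glia call was lost without LIS1+/+ replicate 3 (adjusted p = 0.0986) or LIS1+/- replicate 1 (0.132), the FGF, Notch and hedgehog call without LIS1+/+ replicate 3 (0.0503) or LIS1+/- replicates 1 (0.133) or 3 (0.0723), and that of surface ectoderm, which fell along the course, without LIS1+/- replicate 3 (0.0653). Clone and genotype cannot be told apart.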

How the results depend on the processing

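The alternatives without the 3 libraries apart and with the GC trend removed were chosen only after the data were seen. No named gene changed direction where it passed in the main or the alternative setting, nor did a list in the direction given by its test. Changes of direction where neither setting passed were not counted. The median of the BMP, TGF-beta and activin list at Day 12 went from -0.21 to 0.01 without LIS1+/+ replicate 1. Of the named genes 8094 values under alternatives kept their side of the threshold, 481 lost the call and 232 gained it, and of the lists 1995, 77 and 89. In the settings run other than leaving out 1 library, the gene counts of the 4 stage comparisons stayed within 1.5 times.

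With no filter on low counts the genes that passed numbered 206 in hESC, 412 at Day 5 and 483 at Day 12, the differences 281 (Day 5 minus hESC), 363 (Day 12 minus Day 5) and 172 (Day 12 minus hESC), and the genes shared by all 3 stages 13. In fits of only the libraries compared they numbered 153 in hESC and 41 at Day 12, the first 2 differences 117 and 77, the shared genes 2, the lists 11 in hESC and 7 at Day 12, and PAFAH1B1 at Day 12 stood at -0.80, no longer past the threshold. DESeq2 gave 139 in hESC, 290 at Day 12, and 146 and 111 for Day 5 minus hESC and Day 12 minus hESC. Without the 3 libraries apart, Day 12 gave 381, Day 12 minus hESC 158, and PAFAH1B1 -0.68 at Day 5, now past the threshold, and -0.55 at Day 12, no longer past it. With the GC trend removed, hESC gave 110 and Day 12 minus hESC 70. The cause was not tested. With an estimated correlation 1 list passed at Day 5, 0 at Day 12, 7 from hESC to Day 5 and 5 from Day 5 to Day 12 in LIS1+/+, and with fry 25 and 17 in the latter pair. At Day 12, 1548 genes had an unadjusted p under 0.05.

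Left out in turn, single libraries gave 21 to 41 genes in hESC, 125 to 186 at Day 5, 57 to 332 at Day 12, 1317 to 1921 from Day 5 to Day 12 in LIS1+/-, 31 to 79, 59 to 170 and 11 to 138 for the differences, 3 to 10 shared genes, and PAFAH1B1 at Day 12 from -0.91 to -0.55. The cause was not tested.

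Whether replicate numbers pair the samples stays open. For 4 of 6 libraries in hESC, 0 of 6 at Day 5 and 6 of 6 at Day 12, the residuals correlated best with those of the equal number in the other genotype. The correlations across genes of the residuals of equal numbers in both genotypes were 0.106, 0.0256 and 0.0261 in hESC, -0.0789, -0.157 and -0.0215 at Day 5 and 0.0324, 0.0876 and 0.0504 at Day 12. With the replicate number as a block, Day 12 minus hESC gave 30 genes, and the Day 12 calls of the choroid plexus list (adjusted p = 0.202) and the imprinted list (0.0518) were lost.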

Other observations

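Of the tests in this part, those of the paternal pattern, of MEG9, of the share of crest cells and of other splits of the libraries were chosen only after the results were seen. At Day 5 the protocadherin gene PCDH7 (1.55 ± 0.29) and the phosphatase gene DUSP1 (1.35 ± 0.25) were higher in LIS1+/-, and the activin antagonist gene FST was lower (-0.85 ± 0.20), a call lost without LIS1+/+ replicate 1 or 3 and without LIS1+/- replicate 1 or 3 (adjusted p up to 0.14). At Day 12 the WNT pathway receptor genes FZD8 (-1.73 ± 0.25) and LGR4 (-1.43 ± 0.22) and the secreted WNT antagonist gene FRZB (-1.49 ± 0.26) were lower, as were the stress gene DDIT3 (-1.07 ± 0.23) and the matrix proteoglycan gene BGN (-2.50 ± 0.44), while the membrane linker gene EZR was higher (0.80 ± 0.18). The calls of DDIT3 and EZR were lost without LIS1+/+ replicate 1, without LIS1+/- replicate 3 and in a fit of the Day 12 libraries alone, and that of DDIT3 also without LIS1+/- replicate 1 (adjusted p up to 0.117 for DDIT3 and 0.152 for EZR).

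For the genes that differed at all 3 stages, the tables argue against loss or gain of a chromosome segment that spans most of the neighbouring tested genes (10, or 5 for POLR3K). For 0 of the 8 genes did the median of the neighbours lie beyond 0.4 in the direction of the gene, and for 7 of 8 it lay within 0.2 of 0. A loss or gain limited to the gene itself or to few neighbours cannot be seen by this test. A switch of the DLK1-MEG3 domain to the paternal pattern is not decided by DLK1. DLK1 was higher in hESC (1.32 ± 0.24), which goes with such a switch, and lower at Day 12 (-1.54 ± 0.23), which goes against it. At Day 5 no difference was shown (-0.22 ± 0.22, adjusted p = 0.787 in edgeR). Levels in bulk RNA cannot separate a switch from a change in the cells present. Loss of the maternal RNAs of the domain stays open. MEG8 had 1 count over all libraries. MEG9, another RNA of the domain, had 27 counts in LIS1+/+ and 1 in LIS1+/- in hESC, 55 and 5 at Day 5 and 4 and 0 at Day 12, and passed at 0 of the 3 stages in edgeR (adjusted p of 0.0597, 0.0908 and 0.332, unadjusted p under 0.05 at all 3). DESeq2 gave MEG9 an adjusted p at Day 5 (0.178) and Day 12 (0.326) and none in hESC. Of 100 splits of the libraries 1, the real one, gave as many as 8 shared genes and the highest other gave 0. Other splits of the hESC or Day 5 libraries called 0 genes at those stages, so the number shared was bound to be 0 in them and the splits do not decide on chance. Clone and genotype cannot be told apart.

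For the lower neural crest and mesenchyme genes at Day 12, a library that stands apart in its GC trend is argued against, since the median was -2.01 without LIS1+/+ replicate 2 and -1.66 with the trend removed, against -1.62. The weight of 1 LIS1+/+ library stays open, as the median was -0.87 without LIS1+/+ replicate 1. The share of crest and mesenchyme cells may vary between organoid libraries: 27 of the 29 genes had their highest LIS1+/+ value in replicate 1, against at most 15 in 95 of 100 random lists. Median CPM over the crest list was 36.8, 6.92 and 18.5 in LIS1+/+ and 5.56, 5.83 and 5.27 in LIS1+/-. An effect of genotype or clone stays open beside this.

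With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. As many genes passed in 1 of the 10 in hESC (60, highest other 0), at Day 5 (238, highest other 0), at Day 12 (171, highest other 9), and in each stage comparison (5453, 2990, 5341 and 2020, highest other 0). Splits that mix genotypes or stages put the differences between them into the spread, which lowers their gene counts. These gene counts therefore do not decide on chance. As many lists passed in 1 in hESC (7, highest other 3), 1 at Day 5 (9, highest other 8), 3 at Day 12 (12, highest other 15), 2 from hESC to Day 5 (12, highest other 12) and 3 from Day 5 to Day 12 (9, highest other 12).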
